A study of Homo sapiens with 34 samples.

How the data were processed

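RNA sequencing values of 34 established human B-cell lymphoma cell lines were used, with 1 library per line. Per the labels, 11 lines were mantle cell lymphoma (MCL), 14 were diffuse large B-cell lymphoma of the germinal centre type (GCB DLBCL), 6 were diffuse large B-cell lymphoma of the activated B-cell type (ABC DLBCL) and 3 were Burkitt lymphoma (BL). Total RNA was the starting material and the libraries were made at several points in time, per the labels' protocols. The labels marked 30 lines as re-analysed from earlier data and left 4 unmarked, namely Daudi, HBL-2, MAVER-1 and UPN1. The cell lines served as the replicates of a pathology, so p-values of single genes measure the spread between lines, each seen in a single library. Those of gene lists compare the genes of a list with the other genes, and that of the Fisher exact test takes genes as units.

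The table deposited by the authors held variance-stabilised read counts per gene in log2 units, with 31975 genes in 34 columns. The submitters' processing notes named STAR 2.5.3a, R 3.6.1, DESeq2 1.26.0 and genome build GRCh38, without a role for each. No label or header named the read counter, the annotation release or a gene filter, nor said whether reads were counted by strand. A gene with 0 reads sat at 4.55 in every library, the lowest value of the table. Inverting the transform with that lowest value gave whole numbers of reads, within a tolerance of 0.05, for 100% of the values of every library. The recovered totals ranged from 2.55 to 165 M reads per library, with M for 1e6. The value of a single read was 4.70 in the deepest library and 5.63 in the shallowest. Differences near the lowest value were compressed by the transform, so log2 differences of genes with few reads in a group understated the ratio of reads. Values and differences below are on this scale unless reads are named.

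Genes were kept where at least 3 lines exceeded the lowest value by more than 1 log2 unit, which left 22167 genes. One mean per pathology was fitted to all 34 lines with limma 3.58.1 in R 4.3.3, with an intensity-dependent prior, and 7 contrasts were tested. MCL was compared with the unweighted mean of the means of the other 3 pathologies and with each of them, and the 3 other pathologies were compared in pairs. P-values were adjusted by the Benjamini-Hochberg method over all genes of a contrast, with a threshold of 0.05. Differences are given with the standard error from limma, and group levels as mean ± SD over lines.

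CXCR4 was tested separately by a two-sided permutation test of the difference in means. The test was exact where a group had fewer than 10 lines and otherwise used 100000 resamples, and the 7 p-values were adjusted together by the Benjamini-Hochberg method. In the first of these tests the 11 MCL lines were set against all 23 other lines pooled. A permutation test of the F statistic across the 4 pathologies used 100000 resamples. These tests were run in Python 3.11.15 with NumPy 2.4.6 and checked against SciPy 1.17.1 on simulated values.

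The named genes were CXCR4 and, for MCL against the other pathologies, the 12 highest and 12 lowest differences past the threshold that also passed it in the same direction in at least 2 of the 3 pairwise MCL contrasts. For each pairwise contrast they were the 8 highest and 8 lowest differences past the threshold. Clone-based names, immunoglobulin and T-cell receptor segments, Y-linked genes and XIST were left out, and some genes that met these rules are not reported here. Gene symbols were matched for 31574 of the identifiers. A set of 28 gene lists was tested with camera from limma, with the preset correlation of 0.01 and again with an estimated correlation, and 399 of the 401 list entries were measured. The contrasts, the tests, the rule for named genes and the lists were chosen before the data were examined, while the library classes described next were defined from the values.

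The limma fit was tested on simulated reads drawn for the 22167 genes from the real means and depths. Each gene was drawn independently around 1 mean for all lines, apart from the genes changed. No difference between libraries other than depth was simulated, so the false calls do not cover those that such differences could give. For MCL against the other pathologies, 13.4% of genes changed 2-fold, 41.8% of those changed 4-fold and 53.0% of those changed 8-fold were recovered, with 1 false call. Against GCB DLBCL the shares were 8.96%, 38.8% and 54.5%, with 3 false calls, against ABC DLBCL 2.99%, 38.8% and 40.9%, with 7, and against BL 2.99%, 22.4% and 16.7%, with 13. For ABC against GCB DLBCL they were 5.97%, 40.3% and 45.5%, with 4 false calls, for BL against GCB DLBCL 5.97%, 14.9% and 40.9%, with 8, and for BL against ABC DLBCL 1.49%, 13.4% and 37.9%, with 2.

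A difference between libraries was found in the values. The recovered totals of 8 GCB DLBCL libraries lay between 2.55 and 4.84 M reads, and those of the other 26 libraries between 22.6 and 165 M. A score was formed from 50 genes on each side that best separated these 8 libraries from the other 6 GCB DLBCL libraries, and it was then computed for every library. It put 9 libraries in a second class, the 8 shallow ones and the ABC DLBCL line NU-DUL-1, and 25 libraries in a first class. All contrasts were repeated within the first class. Gene counts, named genes that no longer passed and lists no longer called there are given beside the pooled values.

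The alternatives fixed beforehand were no gene filter, a stricter filter of a mean more than 2 log2 units above the lowest value, quantile normalization, median-centring, fits on the groups compared alone, no intensity trend, a robust prior, a weight per line, the re-analysed lines alone, the re-analysed label as a covariate, a difference of at least 1 log2 unit, and leaving out each line in turn. Those added after the data were seen were leaving out the 8 shallow or the 9 second-class libraries, either class as a covariate, thinning all reads to the 2547498 of the shallowest library, and limma-voom on the recovered reads with and without the 8 shallow libraries. Regroupings of the lines were limited to 100 per contrast. Positions are those of build GRCh38.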

Results

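The series measured the transcriptomes of 34 lymphoma cell lines in the context of CXCR4 as a target of radioligands in mantle cell lymphoma. CXCR4 is the receptor of the chemokine CXCL12 and directs the homing of B cells to bone marrow and lymphoid tissue. The lines comprised 11 of MCL, 14 of GCB DLBCL, 6 of ABC DLBCL and 3 of BL. Recovered depth ranged from 60.1 to 109 M reads in MCL, 2.55 to 108 M in GCB DLBCL, 22.7 to 165 M in ABC DLBCL and 22.6 to 92.4 M in BL. Genes without a read made up 19.9 to 47.4% of the genes of a library, most in the 8 shallow GCB DLBCL libraries, so weakly expressed genes were measured least precisely there.

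The pathology labels were first compared with cyclin D1 and SOX11. CCND1 on chromosome 11 encodes cyclin D1, which is overexpressed through a translocation in MCL, and SOX11 is a transcription factor used as a marker of MCL. CCND1 lay between 12.59 in JVM2 and 17.36 in Z-138 in the 11 MCL lines and reached at most 10.43 in the 23 other lines. SOX11 lay between 9.26 and 13.09 in 10 MCL lines, while JVM2 had 1 read. The highest SOX11 values elsewhere were 8.39 in the ABC DLBCL line HBL-1 and 7.60 in the GCB DLBCL line OCI-Ly7. No line was regrouped by these values.

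**Figure D1:**
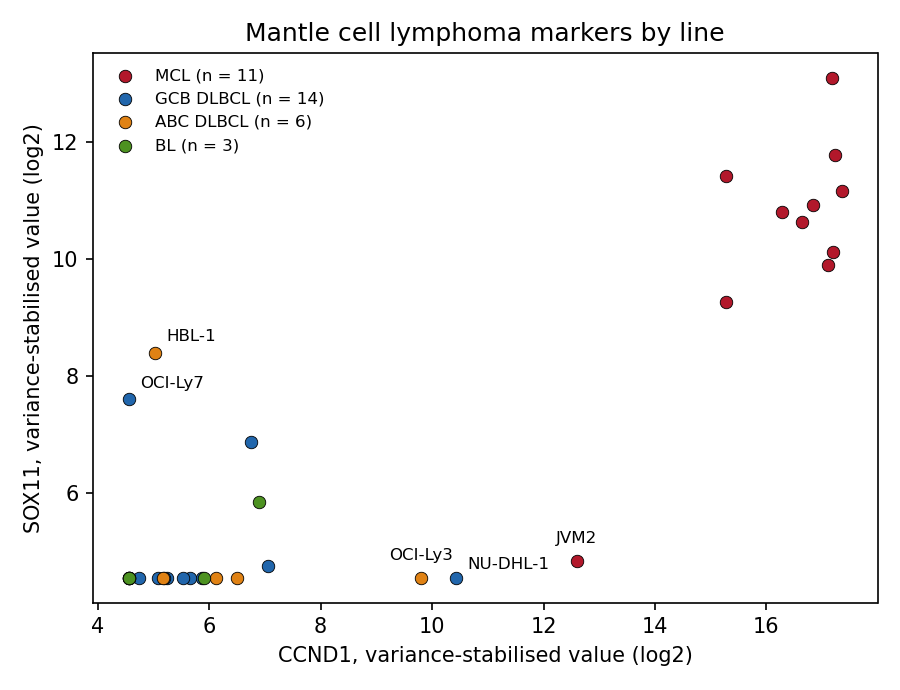
CCND1 on the horizontal axis and SOX11 on the vertical axis, both as variance-stabilised log2 values, with 1 point per line coloured by pathology. The 11 MCL lines lie at CCND1 values of 12.59 and above, with JVM2 apart from the other MCL lines in SOX11, and the 23 other lines lie at 10.43 and below.

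The libraries fell into 2 classes that were largely confounded with pathology. In the 9 second-class libraries ZNF593, which encodes a zinc finger protein, and EMC6, a subunit of a membrane protein insertion complex, had 0 reads, whereas each of the 25 first-class libraries had at least 444 and 554 reads of them. MIF, a cytokine, had at most 7 reads in the second class and at least 881 in the first. ILK, a kinase of cell adhesion, had at most 6 reads against at least 1527. PRR11-AS1 went the other way, with 48 to 479 reads in the second class and at most 1 in the first. These genes were among those that best separated the shallow from the other GCB DLBCL libraries, so their separation within GCB DLBCL is not separate evidence. The libraries of the other pathologies were not used to choose them, and of those NU-DUL-1 alone fell in the second class. The class score was 1.14 to 1.98 in the second class and -5.26 to -3.85 in the first. The second class held 8 of 14 GCB DLBCL lines, 1 of 6 ABC DLBCL lines and no MCL or BL line, so contrasts with GCB DLBCL carried this difference. Fits within the first class set aside this difference alone, and other differences between libraries may remain there. The 4 lines not marked as re-analysed, 3 of them MCL, had the highest scores of the first class.

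**Figure D2:**
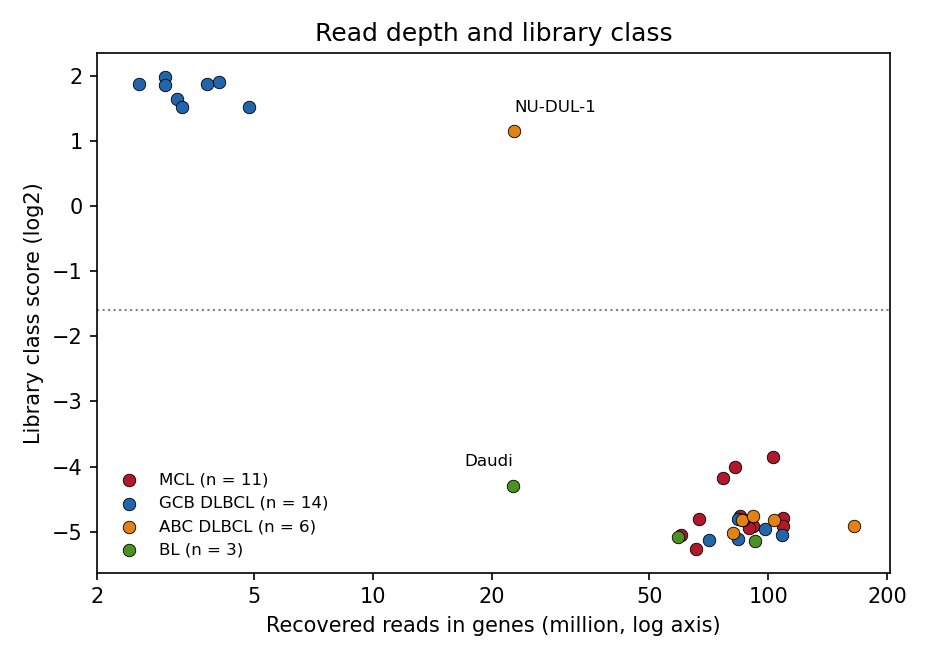
Recovered reads per library on a log axis (M, 1e6 reads) against the library class score in log2 units, with 1 point per line coloured by pathology and the midpoint of -1.60 dotted. The score was built on the GCB DLBCL lines alone, and NU-DUL-1 at 22.7 M reads lies with the shallow libraries while Daudi at 22.6 M lies with the first class.

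The first question was how CXCR4 compared between pathologies. CXCR4 (ENSG00000121966, chromosome 2, 136114349 to 136118149) was expressed in every MCL line, at a mean of 13.49 ± 1.68 (SD, n = 11). The MCL values ran from 10.17 in REC-1, 11.15 in GRANTA519 and 12.10 in HBL-2 up to 14.82 in Z-138 and 15.37 in SP-53. The mean was 11.45 ± 2.80 in GCB DLBCL (SD, n = 14), 12.21 ± 2.31 in ABC DLBCL (SD, n = 6) and 14.46 ± 0.96 in BL (SD, n = 3). The lowest values of the series were 5.64 in DB and 6.08 in Karpas422, from 2 and 4 reads, and the highest was 15.53 in the BL line Ramos. The ranges of the 4 groups overlapped.

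No difference in CXCR4 between pathologies passed the threshold. MCL lay 1.45 log2 units above the 23 other lines (permutation p = 0.11, adjusted p = 0.25), with 8 of 11 MCL lines above the median of the others. The limma contrast, which weights the pathologies equally, gave 0.79 ± 0.85 (adjusted p = 0.64). Against GCB DLBCL the difference was 2.04 ± 0.87 (permutation p = 0.043, adjusted p = 0.24, limma adjusted p = 0.083), with 9 of 11 MCL lines above the GCB DLBCL median. Against ABC DLBCL it was 1.28 ± 1.10 (exact p = 0.21, adjusted p = 0.29, limma adjusted p = 0.80). BL exceeded MCL by 0.97, or -0.97 ± 1.41 as MCL minus BL (exact p = 0.38, adjusted p = 0.44, limma adjusted p = 0.98). BL lay 3.01 ± 1.38 above GCB DLBCL (exact p = 0.068, adjusted p = 0.24, limma adjusted p = 0.31) and 2.25 ± 1.54 above ABC DLBCL (exact p = 0.15, adjusted p = 0.27, limma adjusted p = 0.78). ABC DLBCL lay 0.76 ± 1.06 above GCB DLBCL (exact p = 0.57, adjusted p = 0.57, limma adjusted p = 0.73). Across the 4 pathologies F was 2.41 (permutation p = 0.081).

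Within the first library class the CXCR4 means were 12.27 ± 2.29 in GCB DLBCL (SD, n = 6) and 11.88 ± 2.42 in ABC DLBCL (SD, n = 5), with MCL and BL as before. The 8 second-class GCB DLBCL lines averaged 10.83 ± 3.14, which was 1.44 below the 6 first-class lines (-1.44 as second minus first, exact p = 0.36). MCL exceeded the first-class lines of the other pathologies by 0.89, and all others without the 8 shallow lines by 0.81, against 1.45 pooled (adjusted p of 0.24 to 0.44 over its 6 alternatives). MCL exceeded first-class GCB DLBCL by 1.22 and first-class ABC DLBCL by 1.61, and first-class ABC DLBCL lay 0.39 below GCB DLBCL (-0.39), the opposite direction to the pooled value. None of these last 3 differences passed the threshold, with limma adjusted p of 0.56, 0.50 and 0.98.

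**Figure D3:**
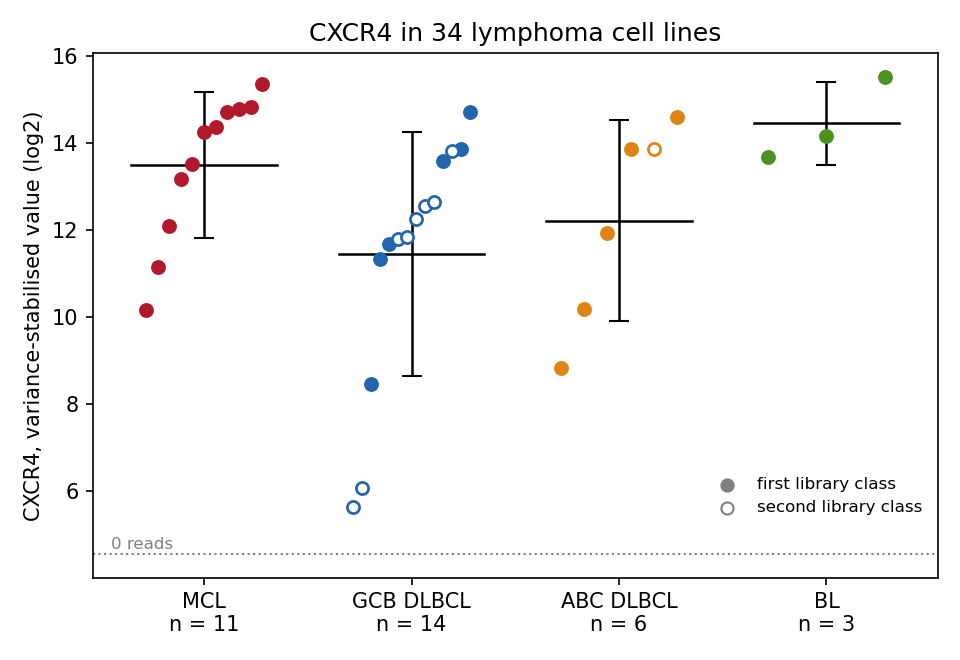
CXCR4 as a variance-stabilised log2 value in each of the 34 lines by pathology, with filled points for first-class and open points for second-class libraries, horizontal lines at the group means and bars of 1 SD. MCL averages 13.49 and overlaps GCB DLBCL at 11.45, ABC DLBCL at 12.21 and BL at 14.46.

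MCL was then set against the other 3 pathologies together. The MCL lines (n = 11, against 23 others) carried more CCND1 (10.38 ± 0.59 log2 units, limma adjusted p = 1.2e-14), CNN3 (6.11 ± 0.30), which encodes an actin-binding calponin, and SOX11 (5.31 ± 0.58). Also higher were ITM2C (6.01), LY6E (5.39), APP (5.37), the amyloid precursor, RNF130 (5.04), a ubiquitin ligase, LILRB4 (4.85), an inhibitory immune receptor, RHOB (4.81), a small GTPase, ASS1 (4.77), an enzyme of arginine synthesis, and MARCKS (4.73), a protein kinase C substrate. The cell cycle kinase CDK6 was lower (-4.93 ± 0.67), with at most 10 reads in 4 MCL lines, as was BCL2L11 (-4.35 ± 0.74), which encodes the pro-apoptotic protein BIM. BCL2L11 had at most 10 reads in 5 of 11 MCL lines and at least 196 reads in each of the 23 lines of the other pathologies. The MCL lines varied widely in BCL2L11 (SD 3.12), from 0 reads in Jeko-1 to 12.92 in MAVER-1, above the mean of 12.01 in the 23 others. Further genes lower in MCL were RGS13 (-4.78), a regulator of G protein signalling, MME (-4.40), which encodes CD10, LINC01991 (-3.17), the monocarboxylate transporter SLC16A7 (-3.11), CADPS (-2.71), PCNX2 (-2.52), USP53 (-2.43), the mTOR inhibitor DEPTOR (-2.32), RGCC (-2.29) and the sphingosine phosphate receptor S1PR2 (-2.24).

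PIMREG, a mitotic regulator, was also higher in MCL (5.31 ± 0.33). It had 785 to 4927 reads in the 11 MCL lines and 0 reads in 19 of the 23 others, whose highest count was 29 in OCI-Ly7. That library had only 3.27 M reads, so its value of 8.39 lay close to the lowest MCL value, 8.79 in MAVER-1. MKI67, a general marker of proliferation, was nevertheless abundant in all lines, at 12.37 or more in the 23 others. Whether annotation or counting accounted for the PIMREG values of 0 reads was not tested, so the difference is given as listed.

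Of the 13 genes in a published MCL signature list, 7 rose in MCL and none fell (9 adjusted over the list alone), among them HDGFL3 (4.28), FARP1 (4.34), PON2 (3.33) and LGALS3BP (3.55), with a camera adjusted p of 9.8e-13. Of 6 diagnostic markers 3 rose (4 adjusted over the list alone), including the receptor tyrosine kinase ROR1 (3.55), with adjusted p = 8.0e-09. Of 18 germinal centre B-cell genes 5 fell and none rose (8 fell adjusted over the list alone), with BCL6 (-4.33), the master repressor of the germinal centre, beside MME, RGS13 and S1PR2. The list's adjusted p was 6.1e-09. Of the 7 classifier genes of the GCB type 2 fell (6 adjusted over the list alone, adjusted p = 5.3e-05). These 4 lists also passed with an estimated correlation, at adjusted p = 9.1e-07, 9.7e-05, 0.0081 and 0.048. They are not separate results, here or in the contrasts below. All 7 GCB classifier genes are also in the germinal centre list, and SOX11 and CNR1 are in both MCL lists.

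The interferon response list moved upward (adjusted p = 0.00045), with 3 of 19 members higher, IRF7 (1.92), IFITM1 (3.30) and USP18 (1.97), and 7 adjusted over the list alone. That call was lost at adjusted p = 0.55 with an estimated correlation. The ABC classifier list moved upward through CCDC50 (3.36) and LIMD1 (1.88), 2 of its 8 genes and 3 adjusted over the list alone (adjusted p = 0.024, and adjusted p = 0.55 with an estimated correlation). The adhesion and homing list was called upward with 0 of 16 members past the threshold (adjusted p = 0.024, and adjusted p = 0.50 with an estimated correlation).

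Among the 18 regulators of the G1 to S transition, CCND1 and the inhibitor CDKN1C (3.95) rose while CDK6 and CCND3 (-1.87) fell, and the list as a whole was not called (adjusted p = 0.52). Of the 16 chemokine and migration receptors tested, S1PR1 (3.44) and GPR183 (3.41) rose and S1PR2 fell (adjusted p of the list 0.069). Of 22 genes of CXCR4 signal transduction, ARRB1 (1.89), an arrestin, rose while RGS13 and the focal adhesion kinase PTK2 (-3.70) fell (adjusted p of the list 0.93). Of 17 surface targets of therapy ROR1 and CD70 (1.76) rose, and the list as a whole was not called.

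In all, 989 of 22167 genes differed between MCL and the other pathologies by limma, 798 higher and 191 lower. Within the first class the number was 881, with 634 higher and 247 lower, and 604 genes were shared with the pooled calls. Each named gene also passed there, while USP18 (adjusted p = 0.073) and CD70 (0.11) did not. CADPS did not pass with the library class as a covariate (adjusted p = 0.071). Median-centring, which moved the median difference of all genes to -0.28, gave 527 higher and 1097 lower, and quantile normalization gave 702 higher and 366 lower. Leaving out the BL line Daudi reduced the number to 619.

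MCL was next compared with GCB DLBCL alone (n = 11 and 14). Beside CCND1 (10.57 ± 0.60, limma adjusted p = 1.5e-14), APP (6.57 ± 0.95), CNN3 (6.14 ± 0.31), ITM2C (5.99 ± 0.89) and LILRB4 (5.71 ± 0.70), the MCL lines were higher in the intermediate filament VIM (5.79 ± 1.14), LY6E (5.69 ± 0.96) and PLAC8 (5.61 ± 0.997). Lower were CDK6 (-5.17 ± 0.69), MME (-5.05 ± 0.86), RGS13 (-4.97 ± 1.01), BCL2L11 (-4.67 ± 0.76), BCL6 (-4.64 ± 0.89), PTK2 (-4.52 ± 0.78), the sorting receptor SORL1 (-4.27 ± 0.74) and ASB2 (-4.05 ± 0.82). These genes kept their direction and passed the threshold within the first class, except ASB2 (-3.78, adjusted p = 0.052).

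Of the MCL signature 6 of 13 genes rose (7 adjusted over the list alone, camera adjusted p = 6.0e-07) and of the diagnostic markers 4 of 6 (4 adjusted over the list alone, adjusted p = 1.3e-05), CD5 (3.05) among them. Both passed with an estimated correlation, at adjusted p = 0.00019 and 0.0021. Of 18 germinal centre genes 9 fell (9 adjusted over the list alone, adjusted p = 1.9e-05), among them ITPKB (-1.78) and MYBL1 (-2.45), and of the 7 GCB classifier genes 6 fell (6 adjusted over the list alone, adjusted p = 7.6e-05). Both stood at adjusted p = 0.060 with an estimated correlation, and at 0.0053 and 0.0027 within the first class.

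Several lists called upward had fewer members past the threshold within the first class. MHC class I rose in 8 of 13 genes (10 rose and 1 fell adjusted over the list alone), with HLA-B (3.09), HLA-C (2.51) and B2M (1.76), at adjusted p = 0.00077, and adjusted p = 0.41 with an estimated correlation. Of the 13 genes 1 passed within the first class, NLRC5, while the list was still called there (adjusted p = 0.0018, median difference 0.78 against 1.37 pooled, and adjusted p = 0.43 with an estimated correlation). NF-kB targets rose in 7 of 20 genes and fell in 1, with CCL3 (4.81) and CCL4 (4.15) highest (7 and 1 adjusted over the list alone), at adjusted p = 0.0027, and adjusted p = 0.47 with an estimated correlation. None of the NF-kB targets passed within the first class, where the list had a camera adjusted p of 0.32. The 10 histone genes tested, whose transcripts mostly lack a poly(A) tail, included 3 that rose (5 rose and 1 fell adjusted over the list alone), with H1-2 at 2.76. Their list stood at adjusted p = 0.022, at adjusted p = 0.47 with an estimated correlation and at 0.21 within the first class. Interferon response (6 of 19, 7 adjusted over the list alone, adjusted p = 0.00047), the ABC classifier (5 of 8, 5 adjusted over the list alone, 0.00047), adhesion and homing (4 of 16, 4 adjusted over the list alone, 0.012) and the chemokine receptors (4 rose and 2 fell of 16, 5 and 2 adjusted over the list alone, 0.026) were also called. With an estimated correlation their adjusted p were 0.47, 0.29, 0.41 and 0.43. Members past the threshold within the first class were 3, 4, 0, and 2 higher with 1 lower, and the 4 lists were called there at the preset correlation but not with an estimated one (adjusted p of 0.29, 0.10, 0.48 and 0.25).

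In all, 5245 genes differed between MCL and GCB DLBCL by limma, 2436 higher and 2809 lower. Within the first class 628 differed, 346 higher and 282 lower, of which 549 were among the pooled calls. That fit had 6 GCB DLBCL lines in place of 14, and how far fewer lines alone lowered the number was not tested. Median-centring gave 1473 higher and 4429 lower, at a median difference of -0.17.

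**Figure D4:**
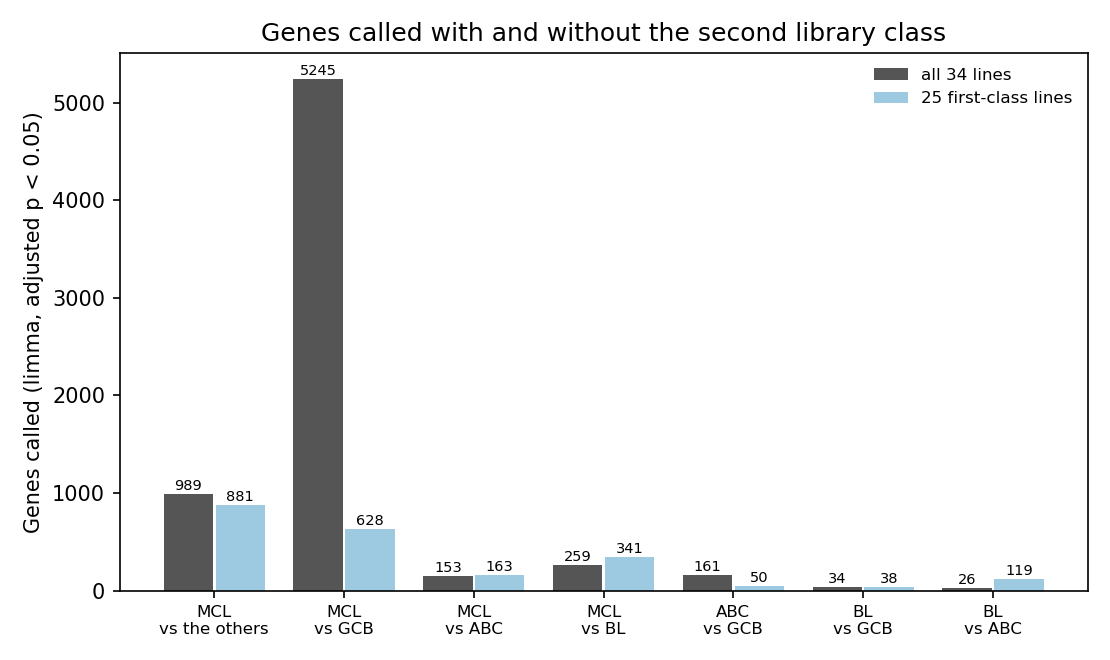
Number of genes past an adjusted p of 0.05 in limma for each of the 7 contrasts, with all 34 lines in dark bars and the 25 first-class lines in light bars. The contrast of MCL with GCB DLBCL fell from 5245 to 628 genes, with 6 of 14 GCB DLBCL lines left, while that of MCL with the other pathologies was 989 and 881.

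Against ABC DLBCL the MCL lines (n = 11 and 6) were higher in CCND1 (10.07 ± 0.76, limma adjusted p = 5.9e-11), CNN3 (6.10 ± 0.39), LY6E (5.72 ± 1.21), the microtubule protein MAP1B (5.25 ± 0.83), RHOB (5.17 ± 0.59), SOX11 (5.16 ± 0.74), ASS1 (4.81 ± 1.09) and PIMREG, which was listed at 0 reads in all 6 ABC DLBCL lines, an effect of annotation or counting not having been tested. They were lower in CDK6 (-4.97 ± 0.87), BCL2L11 (-4.76 ± 0.95), the serine protease TMPRSS6 (-3.33 ± 0.68), SLC16A7 (-3.27 ± 0.68), the pseudogene TUBBP9 (-3.24 ± 0.69), BTBD16 (-2.90 ± 0.68), USP53 (-2.50 ± 0.61) and ERVV-1 (-1.96 ± 0.47). Of the MCL signature 2 of 13 genes rose (6 adjusted over the list alone, camera adjusted p = 7.9e-10) and of the diagnostic markers 2 of 6 (3 adjusted over the list alone, 1.1e-06), with adjusted p = 1.0e-05 and 0.00066 under an estimated correlation. CDKN1C (3.74) rose as well. The mitochondrially encoded list was lower (adjusted p = 0.026, and adjusted p = 0.75 with an estimated correlation), with MT-ND6 (-2.20) as its single member past the threshold and 1 adjusted over the list alone. That list was not called in the re-analysed lines, with quantile normalization or without the 8 shallow libraries (adjusted p = 0.072), but was within the first class (1.1e-07, median difference -0.92 against -0.38 pooled, and adjusted p = 0.29 with an estimated correlation). Adhesion and homing, MHC class I and T-cell genes were called upward with 0 members past the threshold over all genes (1, 0 and 0 adjusted over the list alone), at adjusted p of 0.026, 0.047 and 0.047, and at adjusted p of 0.61, 0.75 and 0.53 with an estimated correlation. MHC class I (adjusted p = 0.098) and T-cell genes (0.068) were not called within the first class.

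In all, 153 genes differed between MCL and ABC DLBCL by limma, 116 higher and 37 lower, and 163 within the first class, 84 higher and 79 lower, with 74 genes in both. Within the first class LY6E (adjusted p = 0.053), ASS1 (0.11), BCL2L11 (0.053), SLC16A7 (0.054), USP53 (0.088) and ERVV-1 (0.054) no longer passed. Median-centring gave 82 higher and 102 lower genes, at a median difference of -0.23. The number was 243 without JVM2, 91 without OCI-Ly10 and 96 without OCI-Ly3.

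Against BL the MCL lines (n = 11 and 3) were higher in CCND1 (10.48 ± 0.97, limma adjusted p = 1.9e-08), ITM2C (8.37 ± 1.44), MARCKS (7.32 ± 1.59), APP (7.07 ± 1.54), HDGFL3 (6.25 ± 0.82), the lysosomal protease CTSB (6.22 ± 0.86), the kinase HIPK2 (6.17 ± 1.45) and LILRB4 (6.16 ± 1.14). They were lower in MME (-6.81 ± 1.40), the growth factor BMP7 (-6.41 ± 1.60), RGS13 (-6.35 ± 1.63), the protein kinase A subunit PRKAR2B (-5.79 ± 1.23), LINC01991 (-5.21 ± 1.09), ADAM23 (-5.04 ± 0.88), CADPS (-4.96 ± 1.303) and WASF3 (-4.87 ± 0.71), a regulator of actin. The MCL signature rose in 4 of 13 genes (8 adjusted over the list alone, camera adjusted p = 1.7e-12) and the diagnostic markers in 2 of 6 (4 adjusted over the list alone, 2.5e-08). Germinal centre genes fell in 4 of 18, MYBL1 (-4.34) and S1PR2 (-4.05) among them (8 adjusted over the list alone, 2.6e-15), and the GCB classifier in 3 of 7 (4 adjusted over the list alone, 2.5e-08). Genes high in BL fell in 2 of 12, BMP7 and RGCC (-4.16), with 3 adjusted over the list alone and adjusted p = 0.00050. These 5 lists passed with an estimated correlation, at adjusted p of 1.4e-06, 0.00017, 0.00027, 0.0043 and 0.045, the last standing at 0.13 within the first class. The ABC classifier (LIMD1, 4.48, 1 of 8 and 2 adjusted over the list alone, adjusted p = 0.0041) and the interferon response (IRF7, 2.77, 1 of 19 and 4 adjusted over the list alone, 0.0068) were called upward, with adjusted p of 0.44 and 0.83 under an estimated correlation.

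In all, 259 genes differed between MCL and BL by limma, 176 higher and 83 lower, and 341 within the first class, 202 higher and 139 lower, of which 207 were in both. Median-centring gave 120 higher and 208 lower genes at a median difference of -0.38, and quantile normalization gave 141 higher and 128 lower. The number was 53 without Daudi, 100 without Raji, 112 without Ramos, 164 without SP-49 and 171 without SP-53.

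ABC DLBCL was compared with GCB DLBCL, the division by cell of origin (n = 6 and 14). ABC DLBCL lines were higher in NIBAN3 (5.26 ± 1.24, limma adjusted p = 0.037), CCDC50 (4.64 ± 1.03), GPM6A (4.51 ± 0.95), tropomyosin TPM2 (4.35 ± 0.91), the adaptor GAB1 (4.27 ± 1.03), the myeloid nuclear antigen MNDA (4.21 ± 0.95), HDGFL3 (4.14 ± 0.62) and NRROS (4.09 ± 0.75). They were lower in BMP7 (-4.85 ± 1.198), the potassium channel KCNN3 (-4.22 ± 0.80), S1PR2 (-4.21 ± 0.74), EEPD1 (-4.17 ± 0.93), NLRC3 (-4.15 ± 0.73), DEPTOR (-4.14 ± 0.79) and the platelet-activating factor receptor PTAFR (-4.08 ± 0.92). The ABC classifier moved upward with 1 of 8 genes past the threshold and 7 adjusted over the list alone (camera adjusted p = 2.0e-08, and adjusted p = 0.044 with an estimated correlation). The GCB classifier moved downward with 3 of 7, S1PR2, ITPKB (-3.17) and MYBL1 (-3.41), and 5 adjusted over the list alone (2.1e-07, and adjusted p = 0.026 with an estimated correlation). The germinal centre list fell in the same 3 genes of 18, with 7 adjusted over the list alone (5.8e-05, and adjusted p = 0.12 with an estimated correlation, or 0.019 within the first class). NF-kB targets rose in 2 of 20, TNFAIP3 (3.48) and NFKBIE (2.17), with 7 adjusted over the list alone (9.9e-07, and adjusted p = 0.40 with an estimated correlation), and neither gene passed within the first class.

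MYC targets, interferon response, BCL2 family and histone genes were called upward with 0 members past the threshold over all genes (1, 0, 0 and 2 adjusted over the list alone). Their adjusted p were 0.00017, 0.033, 0.037 and 0.013, and with an estimated correlation adjusted p was 0.53, 0.60, 0.40 and 0.53. BCL2 family (adjusted p = 0.63) and histone genes (0.27) were not called within the first class. In all, 161 genes differed between ABC and GCB DLBCL by limma, 87 higher and 74 lower, and 50 within the first class, 23 higher and 27 lower, with 26 in both. With low depth as a covariate limma called 0 genes (1763 at an unadjusted p under 0.05, and 166 by limma-voom without the covariate), so every named gene of this contrast lost its call, and with the library class as a covariate it called 26. Without the 8 shallow libraries, however, 159 of the 161 genes kept direction and at least 50% of the difference, at a median ratio of 0.93. NIBAN3 (adjusted p = 0.074), GPM6A (0.075), TPM2 (0.067), GAB1 (0.074), MNDA (0.14) and BMP7 (0.11) no longer passed within the first class. Median-centring gave 126 higher and 60 lower genes. Single lines moved the number widely, to 25 without OCI-Ly10, 46 without OCI-Ly3, 75 without HBL-1, 87 without WSU-DLCL2, 94 without SU-DHL-10 or SU-DHL-4, 98 without SU-DHL-6, 100 without Karpas422, 103 without SU-DHL-5, 105 without DB, 298 without Toledo, 309 without Pfeiffer and 431 without NU-DUL-1.

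BL was compared with GCB DLBCL and with ABC DLBCL, on 3 BL lines. Against GCB DLBCL, BL was higher in PRKAR2B (5.54 ± 1.201), the transcription factor KLF15 (4.95 ± 0.56, limma adjusted p = 2.3e-06), WASF3 (4.37 ± 0.69), ZDHHC14 (4.37 ± 0.95), ADAM23 (4.01 ± 0.86), CASC11 (3.86 ± 0.73), a long non-coding RNA beside MYC, UACA (3.82 ± 0.76) and the neuropeptide NMU (3.48 ± 0.74). BL was lower in CTSB (-4.54 ± 0.84), SPRED1 (-3.78 ± 0.83), ZNF891 (-3.25 ± 0.62), the cytokine receptor IL27RA (-3.25 ± 0.71), the non-coding RNA MALAT1 (-2.88 ± 0.54), ZSCAN9 (-2.85 ± 0.58), ATP6V0A1 (-2.29 ± 0.48) and PRICKLE3 (-2.17 ± 0.47). KLF15 lay between 9.69 and 10.50 in the 3 BL lines and at most at 8.24 in the 31 others. Germinal centre genes, NF-kB targets, plasma cell genes, genes high in BL and MHC class I were called upward with 0 members past the threshold over all genes (0, 0, 1, 0 and 0 adjusted over the list alone). Their adjusted p were 0.015, 0.041, 0.0011, 0.041 and 0.00049, and with an estimated correlation adjusted p was 0.47, 0.68, 0.47, 0.47 and 0.47. Germinal centre genes (adjusted p = 0.078) and NF-kB targets (0.72) were not called within the first class.

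In all, 34 genes differed between BL and GCB DLBCL by limma, 20 higher and 14 lower, and 38 within the first class, 22 higher and 16 lower, with 14 in both. PRKAR2B, ADAM23 and PRICKLE3 (each 0.095), UACA (0.24), NMU (0.18), SPRED1 (0.21), ZNF891 (0.11), IL27RA (0.12) and ATP6V0A1 (0.20) no longer passed there. Median-centring gave 35 higher and 6 lower genes, at a median difference of 0.13, and quantile normalization 59 higher and 16 lower.

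Against ABC DLBCL, BL was higher in DEPTOR (5.80 ± 1.14, limma adjusted p = 0.020), A4GALT (5.42 ± 1.15), the synthase of the BL antigen CD77, ADAM23 (5.33 ± 0.95), MYBL1 (5.30 ± 1.14), KLF15 (5.22 ± 0.62), IFNG-AS1 (4.75 ± 0.98), UACA (4.08 ± 0.85) and ZFAND4 (4.01 ± 0.85). BL was lower in PARP15 (-6.00 ± 1.18), CTSB (-5.28 ± 0.93), LIMD1 (-5.15 ± 0.99), HDGFL3 (-5.03 ± 0.89), RDX (-4.98 ± 0.97), the DNA demethylase TET2 (-4.86 ± 0.97), WSB2 (-4.13 ± 0.81) and RNF213 (-4.003 ± 0.75). The germinal centre list rose with 1 of 18 genes past the threshold and 5 adjusted over the list alone (camera adjusted p = 5.8e-12), and the GCB classifier with 1 of 7 and 5 adjusted over the list alone (3.0e-09), each at adjusted p = 0.0039 with an estimated correlation. The ABC classifier fell through LIMD1, 1 of 8 and 2 adjusted over the list alone (3.2e-05, and adjusted p = 0.15 with an estimated correlation). Plasma cell genes, genes high in BL and MHC class I were called upward and mitochondrially encoded genes downward with 0 members past the threshold over all genes (2, 2, 1 and 1 adjusted over the list alone). Their adjusted p were 0.0038, 0.0034, 0.040 and 0.0034, and with an estimated correlation adjusted p was 0.42, 0.15, 0.59 and 0.59. MHC class I was not called within the first class (adjusted p = 0.12).

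In all, 26 genes differed between BL and ABC DLBCL by limma, 15 higher and 11 lower, and 119 within the first class, 61 higher and 58 lower, with 24 in both. UACA did not pass within the first class (adjusted p = 0.078). The number was 10 without Daudi, 16 without OCI-Ly10, 41 without Raji, 53 without NU-DUL-1 and 55 without SU-DHL-8.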

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

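The tests of the 3 contrasts with GCB DLBCL on thinned reads, of antisense genes above the stricter filter and of sets of 8 left-out lines were chosen after the result was seen, as were the library classes, the fits within them and the 2 strand measures by reads. In the 6 ABC DLBCL lines, 47 genes were examined for a line far from its nearest neighbour by the Dixon gap ratio, and 7 had one. The 2.35 expected by chance assumes normal values and genes chosen without regard to these lines. Most of the genes were named by their differences, and several had lines at the lowest value. The number beyond 2.35 therefore does not mark these lines as unusual. CCND1 was 9.807 in OCI-Ly3, with the next line at 6.50. SOX11 was 8.391 in HBL-1, with the 5 other lines at 0 reads. LY6E was 12.62 in HBL-1, with the next line at 4.96. CDK6 was 9.562 in SU-DHL-8, below the next line at 11.8. KCNN3 was 11.05 in NU-DUL-1, with the next line at 7.20. A4GALT was 7.365 in MD903, with the next line at 5.02. CTSB was 7.576 in SU-DHL-8, below the next line at 10.22.

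The first pattern was the difference between the 8 shallow and the 6 other GCB DLBCL lines, 3447 genes in limma and 7287 in limma-voom, where 1 of 100 splits was as large and the highest other gave 768, so chance was excluded. Low depth was argued against, since 77.7% of the genes were still called with all 14 libraries thinned to the shallowest. Counting without regard to strand was predicted to raise the share of lower genes that overlap another gene. That share was 0.977 of the share among genes not called. Overlap was taken over whole gene spans on any strand, by coordinates that were not those of the submitters' counting. The ratio therefore cannot decide the question for the lower genes. For the higher genes counting without regard to strand remains a candidate explanation. Of them 69.0% overlapped another gene against 59.3% of genes not called, a ratio of 1.16 (odds ratio 1.53, Fisher exact p = 1.1e-05, with genes as units). No prediction was set for overlap of the higher genes, and the limits of the coordinates apply here too, so this ratio cannot decide the question either. Their share with an antisense name was 1.95 times that among genes not called. Among genes above the stricter filter, however, the ratio of 1.55 had an odds ratio interval of 0.83 to 2.72. Of 2 further strand measures, MT-ND6 as a percent of MT-ND5 reads parted the classes, while antisense reads as a percent of partner reads had a median of 1.058% in the first class and 2.23% in the second, with overlapping ranges of 0.70 to 1.75% and 1.14 to 2.82%.

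The second pattern was the number of genes in MCL against GCB DLBCL. Without the 8 shallow lines 53.2% of the genes kept direction and at least 50% of the difference (interval 51.8 to 54.5%), between the bounds set for and against low depth, and 393 turned direction. The interval takes genes as independent units, which they are not, and does not measure the spread between lines. With all libraries thinned, 72.5% were still called, which argued against depth as the whole explanation. For the library class, 1 of 100 sets of 8 left-out lines kept as small a share, the real one, both for genes higher in MCL (72.1%, lowest other 81.0%) and for genes lower in MCL (36.7%, lowest other 52.8%), so the class remains a candidate explanation for part of the genes. For ABC and BL against GCB DLBCL, 98.8% and 100% of the genes kept direction and 50% of the difference, and 61.5% and 73.5% were called after thinning, which argued against depth there.

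The third pattern was the number of genes per contrast beside regrouped lines, with chance taken as excluded where fewer than 5% of splits gave as many genes. Chance was excluded for MCL against the other pathologies (989 genes, highest other split 931), GCB DLBCL (5245 and 905), ABC DLBCL (153 and 114) and BL (259 and 169), with 1 of 100 splits as large in each. It was not excluded for ABC against GCB DLBCL (161 genes, 5 of 100 splits, highest 3313), BL against GCB DLBCL (34 genes, 19 of 100, highest 3118) or BL against ABC DLBCL (26 genes, 5 of 84, highest 540). The splits of 3313 and 3118 genes pointed to a structure of the samples, with 5 second-class libraries in the group of 6 and 3 in the group of 3, but that of 540 genes had 0 and 1, and the rank correlation of calls with class imbalance was 0.31 in the first 2 of these contrasts and -0.16 to 0.02 in the 4 others where it could be computed. Within the first class chance was excluded for MCL against the other pathologies (881 genes, highest other 12, 1 of 100), GCB DLBCL (628 and 13, 1 of 100), ABC DLBCL (163 and 26, 1 of 100) and, by that bound, for ABC against GCB DLBCL (3 of 100), although the highest other split gave 67 genes and the real one 50.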

How the results depend on the processing

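The settings on depth, library class and limma-voom and those of the F test and the CXCR4 association were added after the result was seen, and the cause of moved counts was not tested. CXCR4 passed in 0 of 42 settings by permutation, where its lowest adjusted p was 0.078 (MCL against GCB DLBCL), and its direction turned in 1 setting for MCL against BL (0.08) and in 2 for ABC against GCB DLBCL (-0.39); F was 2.25, 1.72 and 1.62 with quantile normalization, the re-analysed lines and the first class. Without single lines CXCR4 differed by 1.16 to 1.78 (MCL against others), 1.60 to 2.38 (GCB DLBCL), 0.60 to 1.76 (ABC DLBCL), -1.36 to -0.43 (BL), 0.29 to 1.44 (ABC against GCB DLBCL), 2.48 to 3.40 (BL against GCB DLBCL) and 1.57 to 2.72 (BL against ABC DLBCL). Genes in MCL against others numbered 553 with the stricter filter, 1624 with median-centring, 2413 with a weight per line, 554 in re-analysed lines, and 619 (without Daudi) to 1117 (Toledo) without single lines. MCL against GCB DLBCL gave 2474 with the stricter filter, 3331 with weights, 2472 at a difference of at least 1, 543 without the 8 shallow libraries, 368 with low depth as covariate, 628 without the second class, 522 with class as covariate, 2924 with limma-voom, 663 with limma-voom without the 8, and 4107 (Karpas422) to 6129 (Pfeiffer). MCL against ABC DLBCL gave 67 with the stricter filter, 80 with only the groups compared, 772 with weights, 315 with limma-voom, 243 with limma-voom without the 8, and 91 (OCI-Ly10) to 243 (JVM2), with 96 without OCI-Ly3. MCL against BL gave 457 with only the groups compared, 1609 with weights, 41 in re-analysed lines, and 53 (Daudi) to 357 (JVM2). ABC against GCB DLBCL gave 20 with only the groups compared, 721 with weights, 92 in re-analysed lines, 44 without the 8, 0 in limma with low depth as covariate (1763 unadjusted, 166 by limma-voom without it), 50 without the second class, 26 with class as covariate, 50 with limma-voom without the 8, and 25 (OCI-Ly10) to 431 (NU-DUL-1). BL against GCB DLBCL gave 55 without filter, 10 with the stricter filter, 75 with quantile normalization, 8 with only the groups compared, 423 with weights, 52 in re-analysed lines, 238 with that label as covariate, 22 without the 8, 6 with low depth as covariate, 11 with class as covariate, 13 with limma-voom without the 8, and 24 (Karpas422) to 45 (SU-DHL-5). BL against ABC DLBCL gave 14 with the stricter filter, 49 with quantile normalization, 753 with weights, 8 in re-analysed lines, 85 without the 8, 119 without the second class, 75 with limma-voom, 71 with limma-voom without the 8, and 10 (Daudi) to 55 (SU-DHL-8). With an estimated correlation the gene lists called were 4 for MCL against others, 2 against GCB DLBCL, 2 against ABC DLBCL, 2 for ABC against GCB DLBCL, 0 for BL against GCB DLBCL in limma camera (1 unadjusted) and 2 for BL against ABC DLBCL; BL against GCB DLBCL had 3 in re-analysed lines and 3 with quantile normalization. Named genes lost their call in 47 of 120 cases in re-analysed lines, 39 of 96 with only the groups compared, 41 of 120 with limma-voom without the 8, 35 of 120 with low depth as covariate and 287 of 2448 without single lines, and none turned direction with a call. Genes associated with CXCR4 numbered 2 without the second class.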

Other observations

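The search for genes that part all MCL lines from all others and the comparisons of MT-ND6, PIMREG and CDKN1C were chosen after the values were seen, while the association with CXCR4 was planned, without its fits by library class. Of 22167 genes, 5 were higher in each of the 11 MCL lines than in any of the 23 others and 0 were lower in each, where a random order of lines would give 7.0e-07% of genes or 1.5e-04 genes; limma called 191 genes lower, 3897 genes had an unadjusted p under 0.05 in either direction, and limma-voom called 1345. They were CCND1, CNN3, its divergent transcript CNN3-DT (20 to 467 reads in MCL, at most 15 elsewhere), PIMREG, whose 0 reads in 19 other lines were not tested for an effect of annotation or counting, and TRIM72 (182 to 3512 reads in MCL, at most 83 elsewhere), which encodes a membrane repair protein of muscle. Separation was judged on values, since reads depend on depth. The lowest MCL and highest other values were 12.59 and 10.43 for CCND1 and 9.13 and 7.10 for CNN3. They were closer for PIMREG (8.79 and 8.39), CNN3-DT (5.46 and 5.24) and TRIM72 (6.67 and 6.59). CDKN1C, an inhibitor of cyclin-dependent kinases, had at least 47 reads in every MCL line and 0 reads in 12 of the others. Of these 12 lines 8 were second-class libraries, where depth was mostly low, and 4 were first-class. The groups overlapped, with 7.01 in NU-DUL-1 and 6.94 in HT above the lowest MCL value of 6.39 in JVM2. The mean of CDKN1C was 8.98 in MCL and 4.95, 5.24 and 4.90 in GCB DLBCL, ABC DLBCL and BL.

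JVM2 was the MCL line with the lowest CCND1 (12.59) and with 1 read of SOX11, and its median correlation across genes with the other MCL lines was 0.853, the lowest of the MCL lines. SP-49 and SP-53 correlated at 0.979 across genes, above all other nearest pairs of the series. Each counted as a separate MCL line, and no fit left out both. If they are not independent, p-values of the MCL contrasts may be too small. Toledo, a GCB DLBCL line, was nearest to the MCL line UPN1 at 0.941, and the ABC DLBCL lines MD903, NU-DUL-1 and SU-DHL-8 were each nearest to Toledo. Genes are not independent replicates in these correlations. The class scores of the 4 lines not marked as re-analysed were -3.85 in HBL-2, -4.01 in MAVER-1, -4.17 in UPN1 and -4.29 in Daudi, the highest of the first class.

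MT-ND6, the only protein gene on the light strand of the mitochondrial genome, averaged 10.61 ± 0.97 in MCL and 10.74 ± 0.99 in BL against 13.86 ± 0.81 in GCB DLBCL and 12.81 ± 0.57 in ABC DLBCL. Its reads were 13.7 to 27.8% of those of MT-ND5, on the heavy strand, in the 9 second-class libraries and 0.355 to 7.25% in the 25 first-class libraries. The first-class medians were 1.255% in MCL, 4.80% in GCB DLBCL, 2.58% in ABC DLBCL and 1.39% in BL.

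Among lines of the same pathology, 7 genes varied with CXCR4 past the threshold in limma, with 2261 at an unadjusted p under 0.05. RUBCNL (slope 0.85), WWC3 (0.62) and ANO6 (0.48) rose with it, and PKD1L1 (-0.28) and SOX9 (-0.39) fell. Of 100 permutations of CXCR4 within pathologies, 6 gave as many genes, with 1576 in the highest other, so chance was not excluded for this association. The fit did not take the library class into account; with it as a covariate 8 genes were called, the 7 among them, and within the first class 2, none of the 7, although all 7 kept their direction.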
